A study of Mus musculus with 6 samples.

How the data were processed

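Hybridisations of 6 RNA samples on an Illumina mouse whole-genome bead array were analysed, 3 from untreated murine cancer cells that express the rat her-2/neu oncogene and 3 from the same cells given 8 µM withaferin A for 6 h. Per the labels, the cells were grown in medium with 20% serum, the replicates were made at passages 2, 3 and 4, and biotin-labelled total RNA was hybridised. The labels do not tie a passage to a replicate number, and separate treatments at the bench are described only through the passages, so p-values measure the spread between these arrays.

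The authors deposited a table of probe intensity values, 1 per array, that were neither normalized nor background-subtracted as far as the values show. Beside each intensity, the deposited table holds a detection score whose header names a detection p. The score rose with intensity and was read as 1 minus that p. Its steps lie within 5.04e-06 of multiples of 1 over 936, which implies 936 negative control probes. The authors also deposited a value table, which was found from its values to hold log2 intensities centred on the mean of the 2 arrays with the same number, so that the columns of a pair mirror each other to within 1.00e-06. The column medians of that table were -0.000566, -0.00265 and -0.00108 for untreated arrays 1 to 3 and 0.000566, 0.00265 and 0.00108 for withaferin A arrays 1 to 3. Differences within its pairs correlated across probes with those of the values used here at 0.963, 0.966 and 0.961, and the slope of the unnormalized log2 ratio on them was 1.01, 1.11 and 1.05, which sets scale and direction. Its normalization between arrays stays unknown, and the scanner software is not given in the sources used here.

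Intensities were background-corrected with normexp on negative controls inferred from the detection p, given an offset of 16, quantile-normalized and taken to log2 with neqc of limma 3.58.1 in R 4.3.3. Of 45281 probes, 19077 had a detection p under 0.05 on at least 3 of the 6 arrays and were tested. The platform annotation listed 34903 probes, 34885 of them with 1 symbol and 18 with several, and 10378 probes were not listed. Of the probes with 1 symbol, 34807 were found by gene ID in a gene table of assembly GRCm38.p6, which changed 0 symbols. No genome build is named for the array, so no coordinates are printed. Tested probes comprised 16022 with a symbol, for 9756 genes, and 3055 without a single symbol. A gene was represented by its tested probe with the highest mean log2 value. Among the 4068 genes with several tested probes, 0 had probes past the threshold in both directions, and of 257 called genes with several probes, 96 had every probe called the same way.

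Withaferin A and untreated arrays were compared with limma (lmFit and eBayes, two-sided), and p-values were adjusted by Benjamini-Hochberg over the probes tested, with a threshold of 0.05. Errors are SDs over 3 arrays or limma standard errors (SE), and log2 changes are withaferin A minus untreated. The 26 gene lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists, and also with an estimated correlation and with fry. Counts within a list are given over all probes and adjusted over the list alone. Before the data were examined, the groups, the test, the lists, the alternatives to be tried and the rule for named genes were fixed. The paired form of the test on the deposited value table was chosen once its values had shown the centring. The rule took the 6 largest rises and 6 largest falls past the threshold with the same sign in all 3 same-numbered pairs, skipping clone identifiers. It also took up to 3 called members of each list with the largest changes, or the member with the smallest p where none was called, and a fixed set (Hspa1a, Hspa1b, Hmox1, Hsp90aa1, Vim, Erbb2, Nfkbia, H2-K1, Calr, Raet1d, Cd274 and Actb).

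The tests were tried on simulated data built from the 19077 probes for this comparison. Limma recovered 50 of 100 probes changed 2-fold and 91 of 100 changed 4-fold, with 1 false call among 18877 unchanged probes. Camera recovered 20 of 20 shifted lists over 9756 genes and called 1 of 100 unchanged lists. Those lists were random and their genes were simulated independently, so false calls in lists whose genes vary together were not tested. In the measured data the estimated correlation within a list reached 0.84 (hypoxia and glycolysis genes). Alternatives covered background correction, normalization, the deposited value table, the filter on dim probes, the replicate number as a block, the variance model, array weights, probes per gene, the set test and leaving out each array. The number of arrays limits the precision, and changes under 2-fold are often missed at this size.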

Results

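Gene expression was measured in murine cancer cells that express rat her-2/neu, a receptor tyrosine kinase oncogene, with and without withaferin A, a steroidal lactone of the plant Withania somnifera. The series title places the experiment in a study of cellular stress and antitumour immunity, and the comparison asks which transcripts differ after 6 h at 8 µM. Each group held 3 arrays. Median raw intensity over all probes was 81.9, 81.3 and 77.9 on untreated arrays 1 to 3 and 77.1, 77.6 and 78.1 on withaferin A arrays 1 to 3. Over the tested probes it was 234.4, 235.9 and 218.5 on the untreated arrays and 191.8, 202 and 198.2 on the withaferin A arrays. Before normalization every withaferin A array was thus dimmer at the tested probes than every untreated array. Between 18275 and 20104 of 45281 probes per array had a detection p under 0.05. Pearson's r across probes, which are not independent replicates, was 0.979 to 0.985 among untreated arrays, 0.975 to 0.990 among withaferin A arrays and 0.950 to 0.976 between groups. The first principal component held 54.6% of the variance and placed the untreated arrays at -23.7, -35.0 and -38.9 and the withaferin A arrays at 31.1, 45.1 and 21.4.

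The 6 largest rises after withaferin A were of Gsta1, Gsta2, Gsta4, H4c8, Dppa5a and Hmox1. Gsta4, a glutathione S-transferase which conjugates lipid peroxidation products to glutathione, rose from a log2 intensity of 7.14 ± 0.58 to 12.31 ± 0.28 (SD, n = 3 each), a 36.0-fold change (log2 change 5.17, SE 0.28, limma adjusted p = 1.62e-05). Hmox1, the haem-degrading enzyme heme oxygenase 1, rose 20.1-fold (log2 change 4.33, SE 0.21, adjusted p = 9.76e-06). Gsta1 and Gsta2 rose 126-fold and 70.2-fold, but these near-identical paralogs may share signal and each is uncertain. Other probes of Gsta1 had log2 changes of 5.82 and 6.46, against 6.97. Hmox1, Gsta1 and Gsta2 were each above background on 1 of the 3 untreated arrays, so their folds rest on dim baselines. Without background correction Gsta4 rose 23.9-fold, Hmox1 6.87-fold, Gsta1 35.4-fold and Gsta2 20.4-fold, and in the deposited value table the last 3 rose 8.00-fold, 42.8-fold and 24.3-fold. H4c8, a histone H4 gene with near-identical copies, rose 23.2-fold, and Dppa5a, a pluripotency-associated RNA-binding protein gene, rose 20.4-fold from a baseline detected on 2 of 3 untreated arrays. Without background correction these rises were 11.2-fold and 7.54-fold, and 12.6-fold and 8.79-fold in the value table. The ranking of rises depends on background correction. Without it Srxn1 (13.1-fold higher), described below, rose more than H4c8, Dppa5a and Hmox1. Hspb1 (7.68-fold), also described below, then rose more than Dppa5a and Hmox1. In the value table Srxn1 rose 13.4-fold, again more than H4c8, Dppa5a and Hmox1.

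The 6 largest falls were of Fas, Shisa2, Vcam1, Tnfrsf11b, Limch1 and Phactr1. Fas, a death receptor, fell by 2.98 on the log2 scale (SE 0.33, 7.89-fold lower, adjusted p = 0.00108), and its other probe fell by 1.93. Fas was above background on 2 of 3 withaferin A arrays, so its fold rests on a dim level after treatment. Vcam1, an adhesion molecule, fell by 2.75 (SE 0.22, 6.73-fold lower, adjusted p = 0.000154), and Tnfrsf11b, which encodes the decoy receptor osteoprotegerin, fell by 2.63 (6.18-fold lower). Shisa2, an attenuator of Wnt and FGF receptor maturation, was 7.66-fold lower, and Limch1 and Phactr1, which encode actin-associated proteins, were 6.02-fold and 5.63-fold lower. Other probes of Phactr1 changed by -1.76 and -0.75, the last of which did not pass (adjusted p = 0.0681). Without background correction the falls were 3.32-fold for Fas, 3.57-fold for Shisa2, 4.22-fold for Vcam1, 3.05-fold for Tnfrsf11b, 3.94-fold for Limch1 and 3.63-fold for Phactr1, and in the value table those of Fas, Shisa2 and Tnfrsf11b were 3.70-fold, 3.97-fold and 3.34-fold. The ranking of falls also holds only with background correction. Without it Angpt1 (3.74-fold lower), Thbs1 (3.40-fold) and Vegfc (3.40-fold), described below, fell more than Fas and Tnfrsf11b. All 12 genes of the rankings of rises and falls passed in each of the 6 fits that left out 1 array and the 9 alternatives that kept all arrays.

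**Figure D1:**
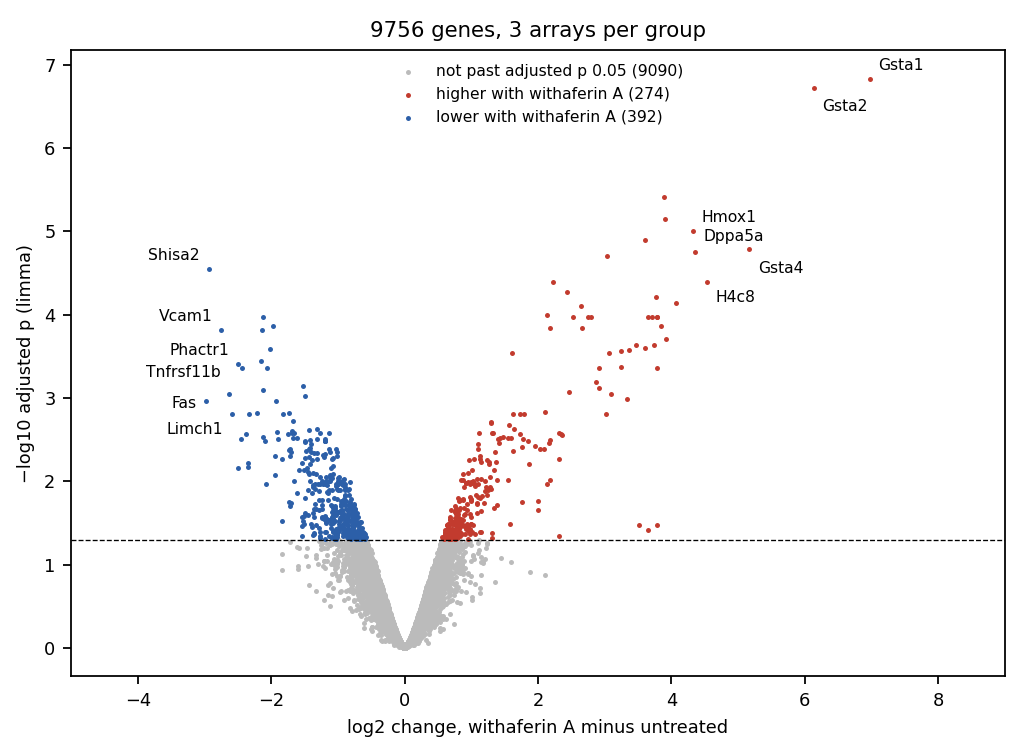
Log2 change (withaferin A minus untreated) against the negative log10 of the limma adjusted p for 9756 genes, 3 arrays per group. Points in red (274 genes) were higher and in blue (392 genes) lower past an adjusted p of 0.05 (dashed line), and the labelled genes are the 6 largest rises and 6 largest falls.

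Across 9756 genes, 666 passed an adjusted p of 0.05, 274 of them higher and 392 lower with withaferin A, and 2532 had an unadjusted p under 0.05. At least 2-fold changes past the threshold numbered 342, with 134 higher and 208 lower. Of the 666 genes, 9 were not above background on any untreated array and 37 on no withaferin A array. Among probes without a single symbol, 64 were higher and 87 lower. The count fell to 436 without untreated array 2 (182 higher, 254 lower), 315 without untreated array 3 (139 higher, 176 lower), 237 without withaferin A array 1 (102 higher, 135 lower) and 319 without withaferin A array 2 (147 higher, 172 lower). Without normalization between arrays the median change over tested probes was -0.22, and 160 genes were higher and 1531 lower. With no filter on dim probes 337 genes passed (172 higher, 165 lower), 2150 with array weights and 2687 in the deposited value table, and 152 were at least 2-fold without background correction. Of the 47 called genes named here by rule, 23 lost their calls with no filter, with the same folds. Changes below are relative to quantile-normalized arrays, whose median change was 0.01.

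Targets of NRF2, the transcription factor of the oxidative stress response, rose as a group. Of 27 measured members, 20 rose, 0 fell and 7 did not pass, and 26 rose when adjusted over the list alone. Beside Gsta4 and Hmox1, Srxn1, which reduces hyperoxidised peroxiredoxins, rose 14.9-fold (log2 change 3.90, SE 0.18, adjusted p = 7.16e-06). The list median was 1.74 (camera adjusted p = 3.52e-27, and adjusted p = 0.0194 with an estimated correlation), or 1.09 without background correction. It was the 1 list of 26 that passed with an estimated correlation.

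Heat shock chaperone genes also rose, 10 of 23 members with 0 lower, and 19 adjusted over the list alone. Hspb1, a small heat shock protein gene, rose 10.3-fold (log2 change 3.37, SE 0.30, adjusted p = 0.000266). Hsph1, a nucleotide exchange factor for HSP70, rose 3.09-fold, and Fkbp4, an HSP90 co-chaperone gene, rose 2.51-fold. Hsp90aa1, the inducible cytosolic HSP90 gene, rose 2.33-fold (adjusted p = 0.0117). The Hsp90aa1 call was lost without withaferin A array 1 (adjusted p = 0.0565) or with no filter (adjusted p = 0.0691), and its other probe changed by 1.19 and did not pass (adjusted p = 0.0659). The inducible HSP70 genes Hspa1a and Hspa1b, near-identical paralogs that the probes may not separate, rose 2.45-fold and 1.88-fold, or 1.43-fold and 1.33-fold without background correction and 1.52-fold and 1.38-fold in the value table. Hspa1a was detected on 1 of 3 untreated arrays, and the Hspa1b call was lost without untreated arrays 1 or 2 or withaferin A arrays 1 or 2, background correction or normalization between arrays, or with no filter (adjusted p up to 0.0801). The other probe of Hspa1b rose by 1.25 on the log2 scale, against 0.91 (adjusted p = 0.00259). Fry called the list (adjusted p = 0.00166), as did camera (median 0.70, adjusted p = 2.66e-12, but adjusted p = 0.0504 with an estimated correlation).

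Genes on the list of ATF4 integrated stress response targets rose in 3 of 29 cases, with 26 not passing and 6 rising when adjusted over the list alone. Slc7a11, the cystine transporter subunit that is also on the NRF2 list, rose 8.10-fold (log2 change 3.02, SE 0.35, adjusted p = 0.00154), with 2.88 and 2.20 at its other probes. Slc3a2, the heavy chain of that transporter, rose 3.00-fold, and Ddit4, an inhibitor of mTORC1, rose 1.92-fold. The rise of Slc3a2 was 1.90-fold without background correction and 2.02-fold in the value table. Its call was lost without background correction, untreated arrays 1 or 3 or withaferin A arrays 1 or 2, or with no filter (adjusted p up to 0.162), and that of Ddit4 without untreated arrays 2 or 3 or withaferin A array 1, or with no filter (adjusted p up to 0.0893). The list median was 0.64, or 0.96 without untreated array 2 and 0.43 without untreated array 3 (camera adjusted p = 4.27e-05, but adjusted p = 0.590 with an estimated correlation). The list mean was 9.91 on untreated array 2 and 9.58 on withaferin A array 3, so the groups overlapped. Of endoplasmic reticulum chaperone and unfolded protein response genes, 0 of 17 passed, adjusted over the list alone or over all probes (median 0.08, or -0.17 without normalization between arrays and -0.0020 without untreated array 3, camera adjusted p = 0.876). In that list Xbp1, a transcription factor of the unfolded protein response, had a change of -0.63 (adjusted p = 0.187), and 1 of the 17 genes passed at an unadjusted p under 0.05. The Xbp1 change was -0.85 to -0.30 with 1 array left out in turn. Calr, the chaperone calreticulin, had a change of 0.14 (SE 0.21, adjusted p = 0.735), or -0.08 without normalization between arrays. That change was -0.06 without withaferin A array 2.

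Proteasome subunit genes rose in 2 of 28 cases, with 26 not passing and 3 rising when adjusted over the list alone. Psmd5, a chaperone of regulatory particle assembly, rose 2.21-fold (adjusted p = 0.00589), and Psmd11, a lid subunit, rose 1.99-fold (adjusted p = 0.0170). The Psmd11 call was lost without withaferin A arrays 1 or 2 or with no filter (adjusted p up to 0.0653). The list median was 0.30, or 0.13 without normalization between arrays (camera adjusted p = 9.93e-05, but adjusted p = 0.579 with an estimated correlation). Sterol synthesis genes rose in 2 of 16 cases, and 5 rose and 1 fell when adjusted over the list alone. Hsd17b7, a 3-ketosteroid reductase of cholesterol synthesis, rose 4.00-fold, and Srebf2, the master transcription factor of the pathway, rose 2.31-fold (1.72-fold without background correction, and a log2 change of 0.70 at its other probe against 1.21). The Hsd17b7 call was lost without background correction, untreated arrays 2 or 3 or withaferin A array 1, or with no filter (adjusted p up to 0.120), and that of Srebf2 without untreated array 3 or withaferin A array 1, or with no filter (adjusted p up to 0.0763). The sterol list median was 0.56, or 0.27 without normalization between arrays and 0.37 with array weights (camera adjusted p = 0.000455, but adjusted p = 0.586 with an estimated correlation).

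Transcripts under NF-kB control fell in 6 of 17 cases, with 0 higher and 11 not passing. Adjusted over the list alone, 8 fell and 1 rose. Beside Vcam1, Nfkbie, an inhibitor of NF-kB and itself its target, fell by 2.38 on the log2 scale (SE 0.30, 5.20-fold lower, adjusted p = 0.00272), and Bcl3, a nuclear cofactor of NF-kB, was 2.98-fold lower (adjusted p = 0.00729). Without background correction Nfkbie was 3.31-fold lower and Bcl3 1.91-fold lower (2.02-fold in the value table), and the Bcl3 call was lost with no filter (adjusted p = 0.0647). Nfkbia, the inhibitor IkB alpha, had a change of -1.11 (SE 0.28) that did not pass (adjusted p = 0.0522). The list median was -0.55 (camera adjusted p = 0.000189, but adjusted p = 0.438 with an estimated correlation), and fry called it lower (adjusted p = 0.0204). That median was -0.31 without untreated array 1, -0.32 without withaferin A array 3, -0.22 without background correction, -0.26 in the value table, -0.25 with no filter and -0.31 with array weights.

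Interferon-stimulated genes had negative changes in all 14 measured members, of which 2 passed, or 8 when adjusted over the list alone. These genes varied together (estimated correlation 0.50), so their signs are not independent. Ifit2, an antiviral translation inhibitor, was 2.70-fold lower (adjusted p = 0.00510; 1.77-fold without background correction and 1.88-fold in the value table), and Ddx58, the RNA sensor RIG-I, was 2.10-fold lower (adjusted p = 0.0278). The Ddx58 call was lost without untreated arrays 1 or 3 or withaferin A arrays 1 or 2, or with no filter (adjusted p up to 0.113). The median was -0.70 (camera adjusted p = 0.000111, but adjusted p = 0.530 with an estimated correlation), or -0.38 without background correction or with array weights, -0.42 in the value table and -0.22 with no filter. Genes of antigen presentation by MHC class I had negative changes in all 16 members, of which 2 passed, or 5 when adjusted over the list alone. Their signs are not independent either (estimated correlation 0.42). Psmb10, an immunoproteasome subunit, was 2.06-fold lower, and Tapbpl, a peptide editor of MHC class I, was 2.02-fold lower (1.57-fold without background correction). The calls of Psmb10 (adjusted p up to 0.155) and Tapbpl (adjusted p up to 0.156) were lost without background correction, untreated arrays 1 or 3 or withaferin A arrays 1 or 2, or with no filter, and that of Psmb10 with median scaling (adjusted p = 0.0502). H2-K1, a classical class I heavy chain, had a change of -0.33 (SE 0.19, adjusted p = 0.309), and its other probe one of 0.20. The H2-K1 change was -0.48 to -0.17 with 1 array left out in turn. The class I list median was -0.49, or -0.21 without withaferin A array 2, -0.30 without background correction and -0.29 in the value table (camera adjusted p = 0.000189, but adjusted p = 0.530 with an estimated correlation).

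Of 12 measured immune receptor ligands and checkpoint genes, 2 fell, 0 rose and 10 did not pass, and 5 fell when adjusted over the list alone. Beside Fas, Cd47, the ligand that inhibits phagocytosis through SIRP alpha, fell by 0.71 on the log2 scale (SE 0.15, 1.64-fold lower, adjusted p = 0.0269). The Cd47 call was lost without untreated arrays 2 or 3 or withaferin A arrays 1 or 2 (adjusted p up to 0.104), and its other probe changed by -0.63 and did not pass (adjusted p = 0.0543). Cd274, the checkpoint ligand PD-L1, had a change of -1.45 (SE 0.47) that did not pass (adjusted p = 0.103) and was detected on 2 of 3 withaferin A arrays. Raet1d, a ligand of the NKG2D receptor, was not above background on any of the 6 arrays and was not tested. The list median was -0.38, or -0.25 without withaferin A array 2, -0.64 without normalization between arrays, -0.60 with the stricter detection filter and -0.048 with no filter (camera adjusted p = 0.0226, but adjusted p = 0.530 with an estimated correlation), and fry called it lower (adjusted p = 0.0485). The camera call was lost without untreated array 3 (adjusted p = 0.0525).

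**Figure D2:**
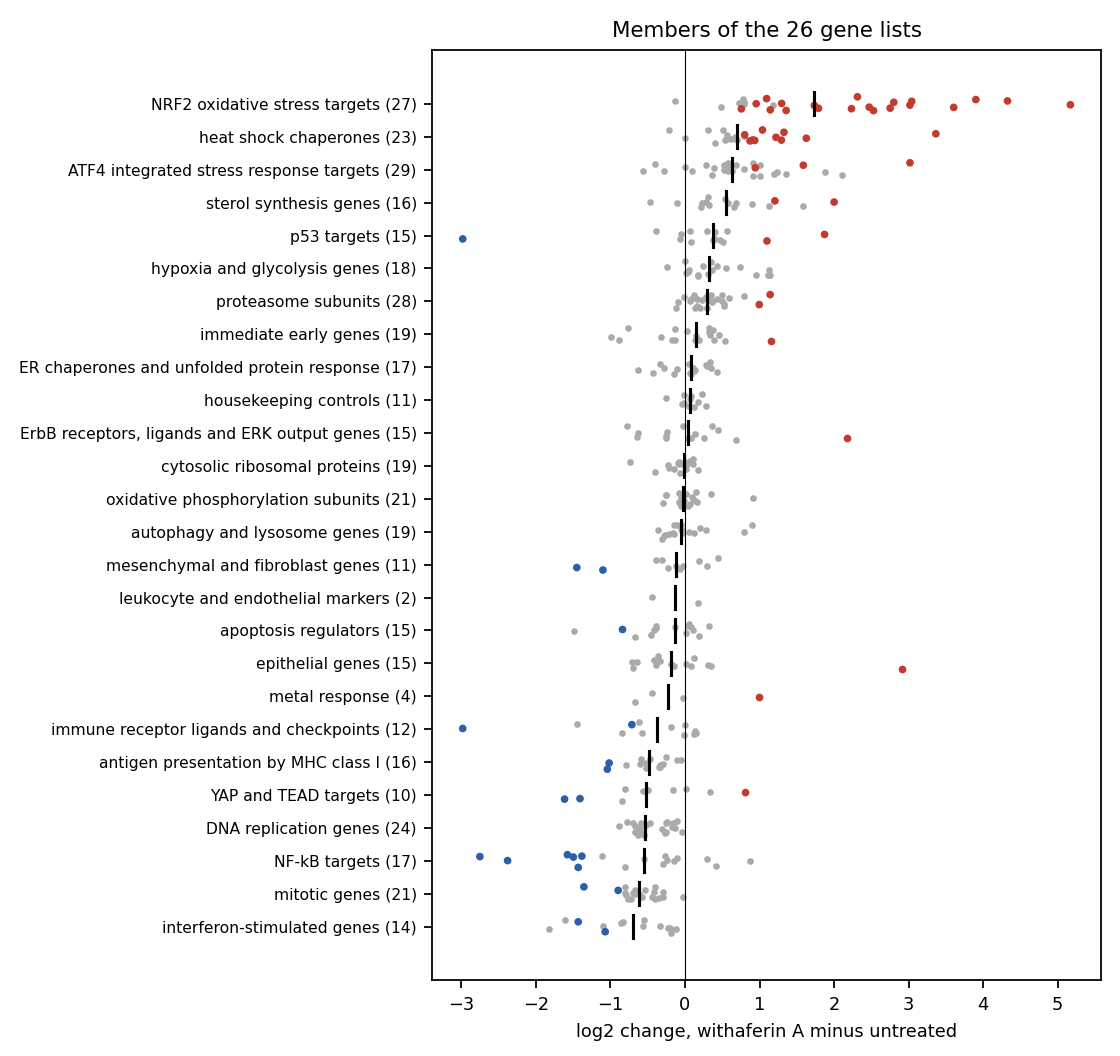
Log2 change (withaferin A minus untreated) of the tested members of the 26 gene lists, with the number tested in brackets. Each point is a gene, in red or blue where it rose or fell past a limma adjusted p of 0.05 and in grey otherwise, and black bars mark list medians, from 1.74 for NRF2 targets to -0.70 for interferon-stimulated genes.

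Mitotic and DNA replication genes had negative changes with few single calls, and the list means of the groups overlapped. All 21 mitotic genes had negative changes, of which 2 passed, or 5 when adjusted over the list alone. These genes varied together (estimated correlation 0.82), so their signs are not independent. The mitotic list mean was 9.97, 9.19 and 9.65 on untreated arrays 1 to 3 and 9.38, 8.67 and 8.97 on withaferin A arrays 1 to 3. Untreated array 2 thus lay below withaferin A array 1. Nusap1, a spindle microtubule protein gene, was 2.56-fold lower (adjusted p = 0.0272), and Kif11, a spindle motor gene, was 1.86-fold lower (adjusted p = 0.0444). Other probes of Nusap1 changed by -1.03 and -0.57, the last of which did not pass (adjusted p = 0.133). The Nusap1 call was lost without untreated arrays 1 or 3 or with no filter (adjusted p up to 0.135), and that of Kif11 without background correction or each array in turn except untreated array 2, or with no filter (adjusted p up to 0.145). The mitotic median was -0.62, or -0.36 with array weights (camera adjusted p = 2.57e-05, but adjusted p = 0.590 with an estimated correlation). All 24 DNA replication genes had negative changes and 0 passed limma's threshold, adjusted over the list alone or over all probes. At an unadjusted p under 0.05, 8 of them passed. The estimated correlation within the replication list was 0.75, so the signs of its members are not independent either. Lig1, the replicative DNA ligase, had the smallest p (change -0.88, adjusted p = 0.0988), and of its 3 other probes 1 passed (-0.87, adjusted p = 0.0450) and those at -0.88 and -0.48 did not. The Lig1 change was -1.11 to -0.53 with 1 array left out in turn. The replication median was -0.53 (camera adjusted p = 0.00128, but adjusted p = 0.705 with an estimated correlation). The camera call was lost without untreated array 1 (median -0.21, mean -0.12, adjusted p = 0.322) or withaferin A array 3 (median -0.36, adjusted p = 0.0725). The replication list mean was 9.96, 8.89 and 9.08 on untreated arrays 1 to 3 and 9.01, 9.01 and 8.56 on withaferin A arrays 1 to 3, so untreated array 2 lay below withaferin A arrays 1 and 2.

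Among 15 p53 targets, 2 rose and 1 fell, with 3 higher and 1 lower when adjusted over the list alone. Cdkn1a, the cyclin-dependent kinase inhibitor p21, rose 3.66-fold (log2 change 1.87, SE 0.28, adjusted p = 0.00611), Plk3, a stress-responsive kinase, rose 2.14-fold, and Fas fell. The Plk3 call was lost without withaferin A array 1 (adjusted p = 0.0507) or with no filter (adjusted p = 0.0528), and that of Cdkn1a with no filter (adjusted p = 0.0676). The list median was 0.38, or 0.25 without background correction, 0.11 without normalization between arrays, 0.15 with no filter and 0.23 with array weights (camera adjusted p = 0.0493, but adjusted p = 0.530 with an estimated correlation). The camera call was lost without untreated array 1 (0.105), untreated array 3 (0.0821), withaferin A array 2 (0.0514) or withaferin A array 3 (0.134), and with median scaling (0.0982), the stricter detection filter (0.0723) or array weights (0.0942). Of 15 apoptosis regulators, Bcl2, which blocks mitochondrial apoptosis, fell by 0.84 on the log2 scale (adjusted p = 0.0299), or by 0.55 without background correction, and 14 did not pass, adjusted over the list alone or over all probes (median -0.13, camera adjusted p = 0.179). The Bcl2 call was lost without each array in turn except untreated array 3, or with no filter (adjusted p up to 0.105). Its other probes changed by -1.07, -0.67 and -0.40, of which the last pair did not pass (adjusted p = 0.146 and 0.493).

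Receptor and growth signalling lists held few called genes, except the list of YAP and TEAD targets. Erbb2, the mouse gene of the HER2 receptor, had a change of 0.44 (SE 0.16) that did not pass (adjusted p = 0.128), and how far its probe reads the rat transgene is not known here. Btc, the ErbB ligand betacellulin, rose 4.49-fold (adjusted p = 0.00343) and was the 1 called gene of 15 on the ErbB and ERK output list, adjusted over the list alone or over all probes (median 0.04, or -0.15 without normalization between arrays and -0.01 without untreated array 3, camera adjusted p = 0.876). The rise of Btc was 2.38-fold without background correction and 2.57-fold in the value table, and its call was lost with no filter (adjusted p = 0.0518). Dusp5, an ERK phosphatase, rose 2.22-fold (adjusted p = 0.0409) as the 1 called gene of 19 immediate early genes, adjusted over the list alone or over all probes (median 0.15, or -0.13 without normalization between arrays, camera adjusted p = 0.459). The Dusp5 call was lost without background correction or each array in turn except withaferin A array 3, or with no filter (adjusted p up to 0.164). Of 10 YAP and TEAD targets, Nuak2, an AMPK-related kinase gene, was 3.06-fold lower (adjusted p = 0.00305), Ccn2, a matricellular protein gene, was 2.65-fold lower, and Ccn1, its relative, rose 1.76-fold. Adjusted over the list alone, 5 fell and 1 rose. The Ccn2 call was lost without background correction, untreated arrays 1 or 2 or withaferin A arrays 2 or 3, or with no filter (adjusted p up to 0.155). The Ccn1 call was lost without normalization between arrays or each array in turn except untreated array 1, or with no filter (adjusted p up to 0.131). Other probes of Ccn1 changed by 0.77 and 0.64 and did not pass (adjusted p = 0.0791 and 0.186). The YAP list median was -0.53, or -0.16 with no filter (camera adjusted p = 0.0293, but adjusted p = 0.530 with an estimated correlation), and its call was lost without untreated array 1 (0.0577), untreated array 2 (0.0555), withaferin A array 3 (0.0725) or normalization between arrays (0.0750).

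Metabolic lists held few calls. Of 18 hypoxia and glycolysis genes 0 passed with limma, adjusted over the list alone or over all probes, and 3 had an unadjusted p under 0.05. P4ha2, a collagen prolyl hydroxylase, had the smallest p (change 1.12, adjusted p = 0.0673), with 1.00 and 0.42 at its other probes. The median was 0.33 (camera adjusted p = 0.0290, but adjusted p = 0.775 with an estimated correlation), and the call was lost without untreated array 2 (median -0.01, adjusted p = 0.916) or withaferin A array 3 (median 0.17, adjusted p = 0.473). Without untreated array 3 it was 0.57 and without normalization between arrays 0.18, and the call was lost with array weights (adjusted p = 0.0677). Of 4 metal response genes, the zinc importer Slc39a10 rose 2.00-fold (adjusted p = 0.0325), adjusted over the list alone or over all probes, and the list had a median of -0.23, a mean of -0.03 and a camera adjusted p of 0.978, with fry's direction upward (adjusted p = 0.912). Slc39a10 was detected on 2 of 3 untreated arrays, and its rise was 1.33-fold without background correction and 1.38-fold in the value table. The Slc39a10 call was lost without background correction, untreated arrays 1 or 2 or withaferin A arrays 1 or 2, or with no filter (adjusted p up to 0.122). Of 19 autophagy and lysosome genes 0 passed, adjusted over the list alone or over all probes, and 2 had an unadjusted p under 0.05, with Gabarapl1, an autophagosome protein gene, at 0.90 (limma adjusted p = 0.0561). The autophagy list had a median of -0.05 (0.01 without untreated array 2), a mean of 0.01 and a camera direction downward (adjusted p = 0.978).

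Lineage lists were compared for signs of other cells, and control lists were examined beside them. Quantile normalization equalizes the arrays, so the control lists cannot show unequal loading. Without normalization between arrays the median change was -0.33, -0.20 and -0.13 in same-numbered pairs 1 to 3. Among 15 epithelial genes, Krt14, a basal keratin, rose 7.55-fold (log2 change 2.92, SE 0.30, adjusted p = 0.000761), or 3.70-fold without background correction and 4.10-fold in the value table, and 14 did not pass (median -0.18, camera adjusted p = 0.468), with 1 higher and 1 lower when adjusted over the list alone. Of 11 mesenchymal genes, Dcn, a matrix proteoglycan, was 2.73-fold lower (adjusted p = 0.00778) and Pdgfra, a PDGF receptor, 2.14-fold lower (adjusted p = 0.0327), adjusted over the list alone or over all probes (median -0.12, camera adjusted p = 0.381). The other probe of Pdgfra changed by 0.02, and the call was lost without background correction, untreated arrays 2 or 3 or withaferin A arrays 1 or 2, or with no filter (adjusted p up to 0.135). The Dcn call was lost with no filter (adjusted p = 0.0614). Vim, the intermediate filament vimentin that withaferin A is known to bind, had a change of -0.23 (SE 0.21, adjusted p = 0.543), and its other probe one of 0.07. With 1 array left out in turn the Vim change was -0.45 to -0.06. Of 16 leukocyte and endothelial markers on the array 2 were tested, and 0 passed with limma and 0 at an unadjusted p under 0.05 (median -0.13, camera adjusted p = 0.891). Cd74, the MHC class II invariant chain, was detected on 2 of 3 withaferin A arrays and had a change of -0.44 (adjusted p = 0.248).

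None of the 19 ribosomal protein genes, 21 oxidative phosphorylation genes and 11 housekeeping genes passed limma's threshold, adjusted over the list alone or over all probes, and 2, 1 and 0 of them had an unadjusted p under 0.05. Rpl22, a ribosomal protein gene, had a change of -0.73 (adjusted p = 0.122), Uqcrq, a complex III subunit gene, one of 0.91 (adjusted p = 0.0700), and B2m, the class I light chain, one of -0.26 (adjusted p = 0.294). Actb, the cytoskeletal actin gene, had a change of 0.08 (SE 0.16, adjusted p = 0.788), or -0.01 without normalization between arrays, and its 4 other probes changed by -0.02 to 0.86 without passing. The ribosomal median was -0.01, or 0.13 with median scaling (camera adjusted p = 0.588). The oxidative phosphorylation list had a median of -0.02, or 0.09 with median scaling, a mean of 0.03 and a camera direction upward (adjusted p = 0.929). The housekeeping median was 0.07, or -0.12 without normalization between arrays (camera adjusted p = 0.876).

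**Figure D3:**
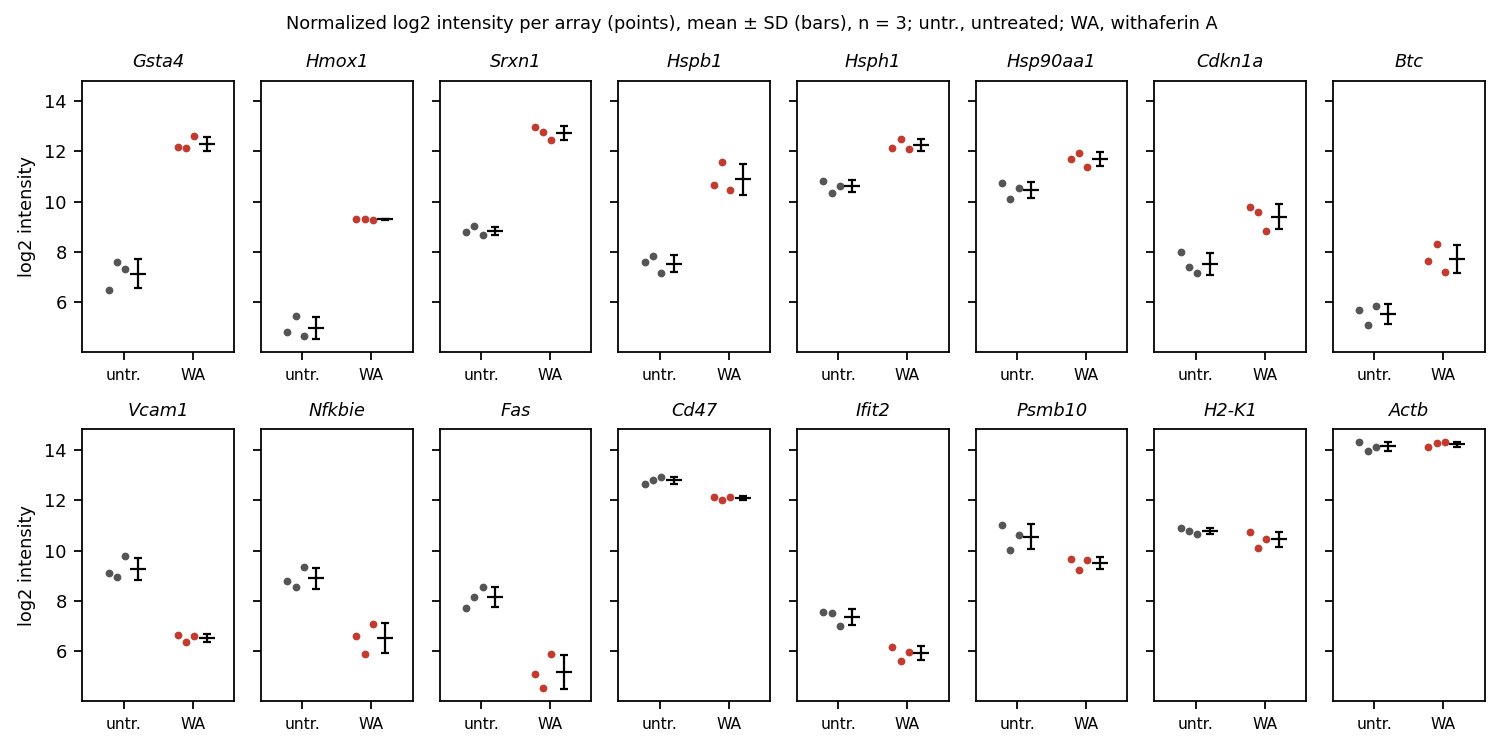
Normalized log2 intensity on each array (points) with mean and SD (bars), n = 3 per group, for 16 genes in untreated cells (untr., grey) and after withaferin A (WA, red). Gsta4 lies at 7.14 in untreated cells and 12.31 after withaferin A, Vcam1 at 9.28 and 6.53, and Actb at 14.14 and 14.23.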

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

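All alternatives here were planned except the counts without histone genes and the paired form of the test on the deposited value table. Of 47 called named genes, 27 passed in all 6 fits that left out 1 array, as did 9 of 14 lists. Under the 9 alternatives that kept all arrays, 24 of the 47 always passed, 23 of them also in the 6 fits. With no filter on dim probes 23 of the 47 lost their calls (adjusted p up to 0.164), without background correction 10 (up to 0.0835), without normalization between arrays 2 (up to 0.117) and with median scaling 1 (0.0502). Changes lay closer to 0 by over 1.5 times, as log2 or fold, for 24 of the 47 without background correction and 16 in the deposited value table. Leaving out 1 array gave 237 to 887 genes (102 to 369 higher, 135 to 518 lower), 232 to 493 at least 2-fold, and 10 to 14 lists. At least 2-fold genes numbered 152 without background correction. Without normalization between arrays 1691 genes passed (160 higher, 1531 lower, 614 at least 2-fold) and the median moved by -0.22. The deposited value table, tested as 3 paired differences, gave 2687 (1218 higher, 1469 lower, 218 at least 2-fold), which include the 666. No filter on dim probes gave 337 (172 higher, 165 lower, 166 at least 2-fold), and array weights 2150 (999 higher, 1151 lower) with a weight of 10.2 on withaferin A array 1. Among genes called both ways, every shared call had the same sign under the 9 alternatives that kept all arrays, with the mean of all tested probes of a gene (580 of 675 calls shared) and in the 6 fits that left one out. These fits reuse the same arrays, so equal signs are little evidence. Of the 666 calls, 292 were shared with no filter, 470 without background correction and 233 without withaferin A array 1. Without the replication-dependent histone genes 636 genes passed. Camera with an estimated correlation called 1 list and fry 4.

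The replicate number as a block gave 1023 genes, 623 of them lower, and changed no list call. Calls of members rose by over 1.5 times, higher in the lists of ATF4 targets (12 against 3), sterol synthesis (5 against 2) and hypoxia (4 against 0), and lower in those of mitosis (9 against 2), interferon (7 against 2), immune ligands (4 against 2), YAP (4 against 2), apoptosis (3 against 1), DNA replication and immediate early genes (each 2 against 0), and by 1 from 0 for oxidative phosphorylation (higher), metal response and ErbB genes (lower). Deviations of same-numbered arrays correlated at 0.267, -0.039 and 0.318, and withaferin A array 2 correlated better with untreated array 1 (0.267) than with its own number. Deviations sum to 0 within each group, so these correlations are not independent and do not decide whether the numbers mark pairs. The main fit left the numbers out because the labels do not tie a passage to a number, although the deposited value table is centred within same-numbered pairs.

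The causes of these differences and of the reversals below were not tested. The called hypoxia list (median 0.33) turned to -0.0070 without untreated array 2, and the other reversals were of genes or lists that were not called. Without normalization between arrays these were Actb (-0.012), Calr (-0.079), ER chaperones (-0.17), immediate early genes (-0.13), ErbB genes (-0.15) and housekeeping controls (-0.12). Median scaling turned ribosomal proteins (0.13) and oxidative phosphorylation (0.091). Array weights turned Actb (-0.047) and oxidative phosphorylation (0.017). No filter turned apoptosis regulators (0.011), ErbB genes (-0.025) and leukocyte markers (0.028). Leaving out 1 array in turn gave Calr changes of -0.063 to 0.36, and medians of -0.0020 to 0.17 for ER chaperones, -0.011 to 0.074 for ErbB genes, up to 0.57 for hypoxia genes, -0.13 to 0.011 for autophagy genes, -0.10 to 0.019 for ribosomal proteins and -0.049 to 0.025 for oxidative phosphorylation. Signal over background limits dim genes: Hmox1, Gsta1, Gsta2 and Hspa1a were detected on 1 of 3 untreated arrays.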

Other observations

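The genes and sets in this part were chosen after their values were seen, and so were all tests except 2 on the histone genes, those of variant histones and of scaling between arrays. The NRF2 list also held Nqo1, a quinone reductase, which rose 12.2-fold (log2 change 3.60, SE 0.18, limma adjusted p = 1.28e-05, n = 3 each), though its other probe changed by 1.08. Gclm of that list, the modifier subunit of the rate-limiting enzyme of glutathione synthesis, rose 8.23-fold. Outside the tested lists, Aldh3a1, an aldehyde dehydrogenase, rose 8.57-fold, and Cyp1b1, a cytochrome P450 that oxidises oestrogens and aromatic hydrocarbons, was 3.32-fold lower (adjusted p = 0.00418).

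The next genes were picked singly, and no list of them was tested. Angpt1, a ligand of the TIE2 receptor, fell by 2.43 on the log2 scale (SE 0.23, adjusted p = 0.000438), and Thbs1, an inhibitor of angiogenesis, fell by 2.33 (SE 0.27, adjusted p = 0.00154). Pdgfc, a PDGF receptor ligand, was 4.16-fold lower and Vegfc, a lymphangiogenic factor, 3.93-fold lower, and these 4 passed in all 6 fits that left out 1 array. Vegfa, a relative of Vegfc, had a change of 0.17 (adjusted p = 0.652). The proliferin genes Prl2c2, Prl2c3 and Prl2c4, near-identical paralogs, rose 12.5-fold, 13.8-fold and 11.4-fold from baselines detected on 2 of 3 untreated arrays. Prl2c2 lay at 7.22, 4.60 and 8.81 on untreated arrays 1 to 3 (SD 2.12). Its rise was 5.69-fold without untreated array 2 and 24.4-fold without untreated array 3, that of Prl2c3 6.31-fold and 26.6-fold, and that of Prl2c4 5.67-fold and 21.0-fold. Their calls were lost without untreated array 1 or any of withaferin A arrays 1, 2 and 3 (adjusted p up to 0.0928), with no filter on dim probes (up to 0.198) and with a trended, robust variance (up to 0.0739). The rises of Prl2c2, Prl2c3 and Prl2c4 were 7.03-fold, 7.85-fold and 6.42-fold without background correction, 7.51-fold, 8.41-fold and 6.88-fold in the deposited value table, and 8.34-fold, 9.13-fold and 7.30-fold with array weights. The other probe of Prl2c2 changed by 2.66, and Pdgfc was 2.67-fold lower without background correction.

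Of 48 tested replication-dependent histone genes, a set chosen for its rises, 30 were higher, 0 lower and 18 did not pass (median 2.11). All 11 H2B genes (median 3.78), 9 of 11 H4 genes (median 3.25), 5 of 9 H3 genes (median 0.98, or 0.39 without background correction) and 4 of 15 H2A genes rose (median -0.11, or 0.052 with median scaling, 0.16 with array weights, 0.21 without untreated array 1 and 0.048 without withaferin A array 2), and near-identical copies make the number of separate transcripts uncertain. Without normalization between arrays the set's median was 1.83, which argues against scaling. With normalization 3 of 5 classes had a median above 1 (H2B, H4 and H1, the last of only 2 genes, H1f2 at 3.77 and H1f5 at 0.18). This argues against signal from 1 class, as H2B and H4 both rose. The 6 variant histone genes had changes of -0.64 to 0.62, and 1 of them, H2aj, was called higher (0.62). Their median of 0.0915 (-0.013 without normalization) argues against a general rise of histone transcripts. More cells in S phase were tested in 4 forms, tried one after another with the values known, and stay open: the DNA replication list median was -0.53 (-0.21 without untreated array 1), and the H2B mean rose by 2.94 more than the mean of all 15 H2A genes, by 3.55 more than that of the 10 brightest (0 higher, untreated level 13.5) and by 1.71 more than that of the other 5, which lie near background (5.71) and of which 4 rose (median 1.76). Also open is a candidate explanation that was not tested, a change in polyadenylation of these transcripts, which oligo(dT) labelling, if it was used here, could read as a rise.

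The level of ATF4 targets differed between untreated arrays: the list mean was 9.18, 9.91 and 8.61 on untreated arrays 1 to 3 and 10.28, 10.17 and 9.58 on withaferin A arrays 1 to 3. Without normalization between arrays the untreated range was 1.43, which argues against scaling. A state shared by same-numbered cultures could not be decided, since 2 of the 3 numbers deviated with the same sign in both groups. No biological explanation was tested.

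The 6 arrays can be split into 3 and 3 in 10 ways, so no share under 0.1 can be reached. The real split called 666 genes and 342 at least 2-fold, each matched by 1 of the 10 splits, the real one, and the highest other split called 0 of each. In the 9 other splits limma called 0 genes each, with 56 to 1189 at an unadjusted p under 0.05 against 2532 in the real one. Each of these 9 splits mixed untreated and withaferin A arrays in both groups, so a treatment effect would itself widen the spread within groups. Their 0 calls thus do not measure what arises without a treatment effect, and no conclusion is drawn from them. The real split called 14 lists, and the highest other split also called 14, so 2 of 10 splits called as many. Camera with a preset correlation called 6 to 14 lists in each of the 9 other splits, so its number of calls does not set the real split apart. Those splits hold unequal numbers of treated arrays and keep part of any treatment difference. Their calls therefore cannot show how many lists pass without a treatment effect. The preset correlation was 0.01, against estimates of up to 0.84 within the lists. With the estimates 1 list passed in the real split. The cause of the calls in the other splits was not tested.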
